A study of Mus musculus with 7 samples.

How the data were processed

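CUTAC libraries of mouse bone marrow cMoPs were made with a commercial CUT&Tag kit under no-salt tagmentation and read from both ends over 150 bp, per the labels' protocols. The files used here are peak lists of 5 of the 7 samples, each of a single library, so these peaks were called per sample and not on pooled samples. The submitters' processing notes name Trimmomatic, Bowtie2, SAMtools, Picard, MACS2 version 2.2.9.1 and the mm10 build. Their settings, the handling of duplicates and the control, if any, are not given in the sources used here. Each entry of the authors' lists holds a score, which is 10 times the −log10 q cut to a whole number. It also holds the fold of the pileup over the local background as the authors' caller gave it, a linear ratio within that library. The third kind of value is the −log10 of the p and of the q of the summit, as deposited. The last is the offset of the summit from the start of its interval, as deposited. These are the authors' own values per peak, and were used to rank and filter peaks within a list. The lowest −log10 q was 1.00 to 1.02 in the 5 lists, so the caller's limit on q was near 0.1. The track line of the list of DE replicate 1 names DE replicate 2, as does that of DE replicate 2. Its sample was taken from the record of the series, and the 2 lists differ (Jaccard index 0.504).

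Entries that share an interval are summits of one peak and were counted once, by their strongest p. The 19 autosomes, X and Y were used for lengths of lists and overlaps, and the autosomes for regions. Regions are the merged union of touching or overlapping intervals of the 4 H3K4me2 lists, and a region was called in a library when it shared at least 1 bp with a peak. No list of problem regions was applied, and no sequence was used. Genes came from a RefSeq table of GRCm38.p6, the mm10 build, which gives gene bounds and no strand. The design, fixed before the data were examined, spoke of transcription starts. Both ends of each protein-coding gene were used in their place, so gene-end regions (within 1 kb) include 3' ends. A region was assigned to the gene with the nearest end within 100 kb, and the strongest regions to the nearest gene at any distance. All 251 genes of the 16 fixed lists were found in the table. Coordinates are counted from 1.

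Lengths of lists were compared as mean log2 values with an exact two-sided permutation test over 6 assignments, and overlaps by the Jaccard index over bases with the 3 splits of the 4 libraries. With 2 libraries per genotype neither exact test can go below p = 0.333. Loss in DE was tested among regions called in both WT libraries, with a sum of hypergeometric distributions over strata of 10 WT rank classes by gene end or other, two-sided, and Benjamini-Hochberg adjustment over the 16 lists. Rank is the mean place by −log10 p as a share of each WT list. Shares have 95% Wilson intervals, which cover counting error only. All H3K4me2 libraries are of batch 2, so the genotypes were compared within 1 batch. The text names the 10 strongest regions of each genotype pattern, at most 6 genes per list in the order fixed, and at Zeb2 the regions at the gene end and the 8 called in the fewest lists. Exceptions are stated where they occur. Alternatives were a −log10 q of at least 5, lists of equal length, 50% cover or reciprocal overlap, merging within 500 bp, other distances, tests without strata, the replicate block and leaving out each replicate.

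Read totals are not in the lists, so depth was inferred. The caller writes its fold as pileup plus 1 over background plus 1, and p as a Poisson tail, so both together give the pileup and the background. In each list the pileups were whole multiples (within 0.01 fragments) of one unit and the backgrounds followed steps of one control fragment, from which depth relative to the background library follows. Of the summits, 99.3% to 99.98% gave a solution. In samples of the lists, 63.0% to 68.8% of summits fell on the background steps, and 0% to 1.4% did so with a wrong unit. The shortest interval of a list, taken as its fragment length, was 74 and 91 bp in WT, 109 bp in both DE lists and 96 bp for H3K4me3. It thus differed between the genotypes, and its effect on the lists was not tested. The genome background per 1000 bp of fragment length was 3.83 to 3.85 in all 5 lists, as one shared background library would give. No header records that library, so this is an inference from the values. At a background of 1, the fewest fragments in a called summit were 6 and 7 in WT, 8 and 9 in DE and 27 for H3K4me3. These numbers are not scaled to depth. In the pileup 1 fragment counted as 1 and 0.963 in WT, 0.834 and 0.679 in DE and 0.263 for H3K4me3. The higher numbers in DE therefore do not show a stricter limit there.

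The code was tested on simulated data. For lists of 30 regions, 4% of 200 sets without an effect had p under 0.05, and 89.5% of sets with loss at 10% of the usual share. For the gene-end comparison over 18854 regions these were 4% without an effect and 100% with loss at 80% of the usual share. Loss was drawn for each region alone, and the members of the simulated lists were drawn at random over the regions. Regions of the fixed lists lie side by side at few genes (28 at 7 genes for granulocytes). The simulated rates need not hold for them. For 39395 simulated regions with 200 planted losses in DE and no other difference, lists as long as those deposited returned 100% of the losses, with 3479 other regions of the WT pattern and 20 of the DE pattern. Lists of equal length returned 94%, with 554 and 642 others. In both simulated sets of 3000 summits, 100% of the fragment numbers were recovered. There every background lay on a step or at a fixed genome value, as it did for 63.0% to 68.8% of summits in samples of the real lists. Recovery at the remaining summits was therefore not tested. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.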

Results

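Histone H3 marks were profiled by CUTAC in sorted mouse bone marrow common monocyte progenitors (cMoPs), the committed precursors of monocytes. CUTAC is an antibody-guided tagmentation assay run at low salt, which cuts accessible DNA beside the mark. The mice carried either the WT form or the variant labelled DE of an enhancer placed at −165 kb from Zeb2, the gene of an E-box-binding transcription factor. The labels list 7 samples, and peak lists of 5 were analysed. These were H3K4me2, a mark of promoters and enhancers, in 2 WT and 2 DE libraries of batch 2, and H3K4me3, a mark of active promoters, in 1 WT library of batch 1. The IgG cMoP library and the H3K4me3 library of cells labelled MDP had no peak list among the files used and were not analysed here. The H3K4me2 lists held 32354 and 28152 peaks in WT replicates 1 and 2 and 21968 and 17079 in DE replicates 1 and 2. The H3K4me3 list held 6425. Depth relative to one background library, inferred from the peak values, was 0.477 and 1.04 in WT, 1.20 and 1.47 in DE and 3.81 for H3K4me3. No label states that replicates came from separate animals, so the permutation p-values for list length and overlap measure only the spread between these libraries. The p-values of the stratified tests are over regions and measure no spread between libraries.

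**Figure D1:**
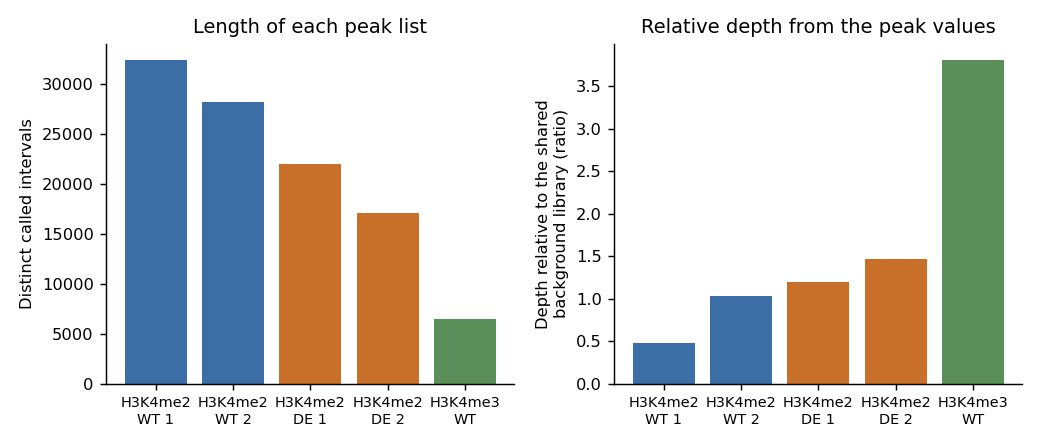
Left, the number of distinct called intervals in each of the 5 peak lists; right, the depth of each library relative to the shared background library (ratio, no unit), as inferred from the peak values. Each bar is 1 library, blue for H3K4me2 WT, orange for H3K4me2 DE and green for H3K4me3 WT; both DE lists (21968 and 17079 peaks) are shorter than both WT lists (32354 and 28152), while the DE depths (1.20 and 1.47) are above the WT depths (0.477 and 1.04).

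The lists outline the chromatin of the sorted cells. Peaks within 1 kb of a gene end were called in all 4 H3K4me2 lists at Csf1r, the receptor for macrophage colony-stimulating factor, Ly6c2, a surface marker of monocytes, and Klf4 and Irf8, transcription factors of the monocyte lineage. The granule protease and peroxidase genes Elane, Mpo, Prtn3 and Ctsg were called in all 4 as well, and all of these genes also carried an H3K4me3 peak. Kit, Gata2, Meis1 and Mecom, genes of early progenitors, had H3K4me2 calls in all 4 lists and no H3K4me3 call. The housekeeping gene Hprt had the same calls. H3K4me3 was called at 2 of the 18 stem and progenitor genes, 9 of the 25 monocyte and macrophage genes and 63 of all 251 listed genes. Its list is short, so a missing H3K4me3 call does not show that the mark was absent. Ccr2, a chemokine receptor of mature monocytes, had its one H3K4me2 region at 124103275 to 124103642 of chromosome 9, 1357 bp from a gene end and thus outside the 1 kb window, and it was called in all 4 lists.

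Fewer genes of lymphoid and mast cell lineages were called, though the myeloid lists were not called in full either. Of 25 monocyte and macrophage genes, 14 and 16 were called in WT replicates 1 and 2 and 15 and 12 in DE replicates 1 and 2. Of 21 granulocyte genes these were 7 and 8 in WT and 9 and 11 in DE. No test was run on these counts. Of 14 B cell genes, 1 was called in WT replicate 1, 1 in WT replicate 2, 2 in DE replicate 1 and 1 in DE replicate 2. Cd79b, a chain of the B cell receptor complex, was the gene called in all 4, and Pax5, a transcription factor of B cells, was called in none. Of 14 T cell genes, 2, 3, 2 and 0 were called in the same order of libraries, and of 13 genes of mast cells, basophils and eosinophils 0, 0, 1 and 0. Of 13 NK and innate lymphoid genes 2, 2, 2 and 3 were called, and of 17 erythroid and megakaryocyte genes 4, 5, 5 and 5, with Tfrc, Gp9, Nfe2 and Zfpm1 called in all 4 (the last 3 singled out after their values were seen). In contrast, 17, 17, 16 and 15 of 17 cell cycle genes had a call, Mki67 and Ccnb1 among those called in every list.

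**Figure D2:**
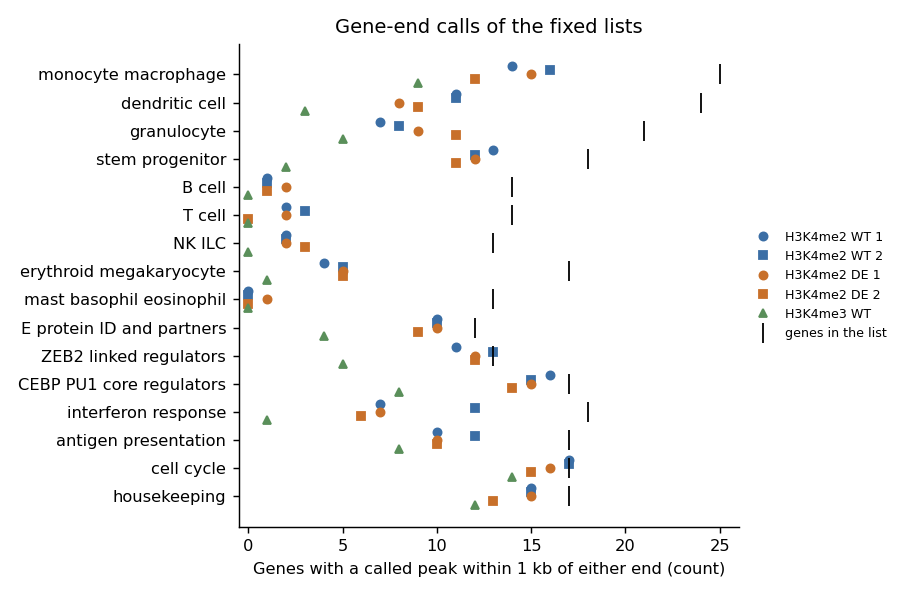
Number of genes of each fixed list (rows) with a called peak within 1 kb of either gene end (horizontal axis, count), one symbol per library; vertical ticks give the number of genes in the list. In the H3K4me2 lists 15 to 17 of the 17 cell cycle genes and 1 or 2 of the 14 B cell genes had a call.

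The first question was whether calls at Zeb2 itself differed between the enhancer variants. Zeb2 (gene ID 24136) lies at positions 44983512 to 45117442 of chromosome 2 (mm10), and 15 regions were called in it or within 300 kb of either end. The regions clustered near the end at the higher coordinate, where 6 H3K4me3 regions were also called. WT replicates 1 and 2 had calls in 9 and 11 of the regions, and DE replicates 1 and 2 in 8 and 7. All 4 H3K4me2 lists shared 6 regions, and 0 regions were called in both libraries of one genotype and neither of the other. The region over the higher gene end, 45117052 to 45117587, was called in all 4.

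No list had a peak within 5 kb of the labelled distance beyond either end of Zeb2. The nearest call was in WT replicate 1 alone, at 45264846 to 45264926, and lay 17.5 kb from the point on the higher-coordinate side. The base from which the label counts −165 kb is not given in the sources used here, so these windows need not hold the enhancer. Of the other regions called in few lists, 45137865 to 45137947 and 45113814 to 45113917 were called in WT replicate 1 alone. The regions 44981726 to 44981879, 45108436 to 45108539 and 45115740 to 45115919 were called in WT replicate 2 alone. The region 45106069 to 45106220 was called in WT replicate 2 and DE replicate 1, and 45109164 to 45109487 for H3K4me3 alone.

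**Figure D3:**
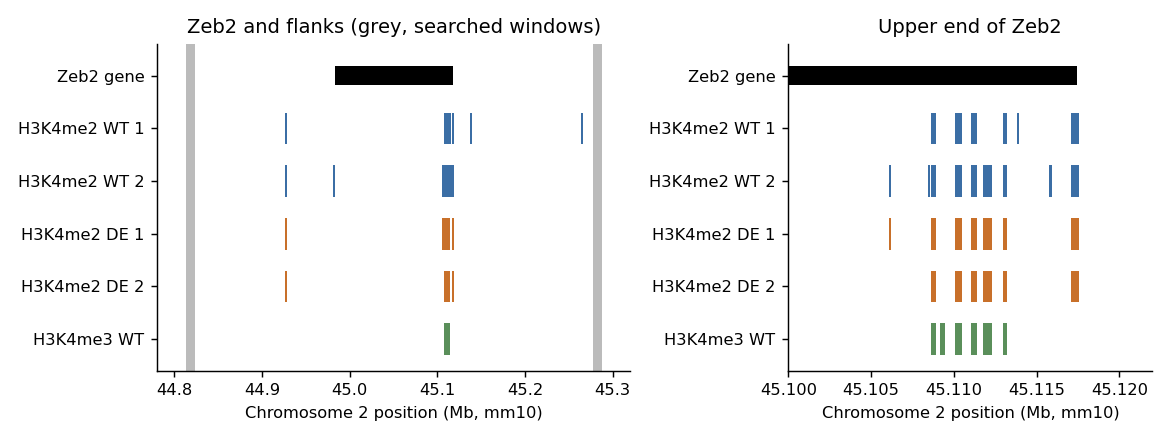
Called regions at Zeb2 in the 5 lists, on the position along chromosome 2 (Mb, mm10); left, the gene with its flanks, and right, the end at the higher coordinate. The black bar is the gene, coloured boxes are called regions (short ones widened to stay visible) and grey bands are the windows at the labelled distance beyond each end, in which 0 lists had a peak.

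The second question was how much the H3K4me2 landscape differed between WT and DE cMoPs. The DE lists were shorter, with 19524 ± 3457 peaks (SD, n = 2) against 30253 ± 2971 in WT (SD, n = 2), a ratio of 0.642 or −0.64 on the log2 scale. Both DE lists were shorter than both WT lists, and the exact two-sided permutation test gave p = 0.333, the smallest value that 2 against 2 libraries allow. On average, pairs of lists of one genotype overlapped slightly more than pairs across genotypes. The WT pair, however, overlapped less than WT replicate 2 with DE replicate 1 (0.497). The Jaccard index, the shared bases over all covered bases, was 0.455 for the WT pair and 0.504 for the DE pair, and 0.361 to 0.497 for the 4 mixed pairs. The mean within genotypes exceeded that between them by 0.0563 (exact permutation p = 0.333, again the smallest possible).

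Of 39395 autosomal H3K4me2 regions, 11891 were called in all 4 lists. In the lists as deposited, 3456 regions were called in both WT and neither DE library, and 432 in both DE and neither WT library, so that 88.9% of these had the WT direction. The direction turned with lists of equal length. When each list was limited to its 17079 strongest peaks, 929 regions had the WT pattern and 1087 the DE pattern, a WT share of 46.1%. Equal lengths hold the totals of the genotypes alike, so this split does not show whether list length or loss set the direction. Simulated lists as long as those deposited, with 1 assumed level of noise, gave 3479 regions of the WT pattern and 20 of the DE pattern beyond the planted losses. The simulated strengths came from these same lists. The 20 lay far below the 432 called, so this level of noise does not describe the data. The nearness of 3479 to 3456 therefore does not show that list length set the WT count. At a −log10 q of at least 5 the counts were 2692 and 99. The other ways to split the 4 libraries gave 645 and 383 regions (replicates numbered 1 against those numbered 2) and 285 and 1030 (WT 1 with DE 2, against WT 2 with DE 1). With the pattern read from 3 libraries, the WT count was 8308 without WT replicate 1, 11846 without WT replicate 2 and 6318 without DE replicate 1. The DE count was 720, 1212, 1550 and 3379 without WT replicates 1 and 2 and DE replicates 1 and 2.

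**Figure D4:**
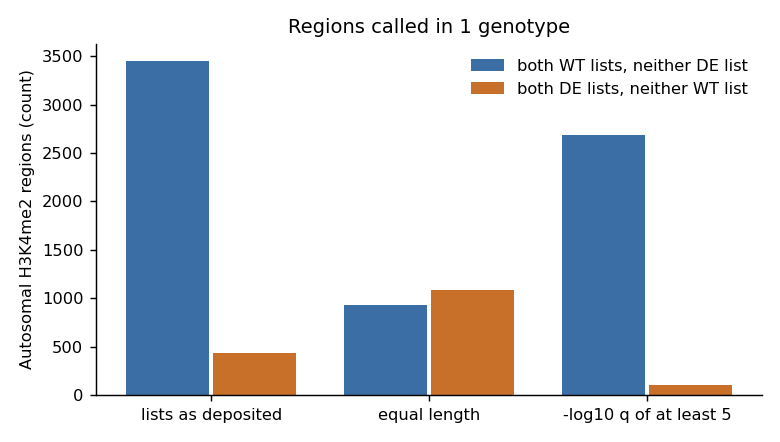
Autosomal H3K4me2 regions (vertical axis, count) called in both WT and neither DE list (blue) or in both DE and neither WT list (orange), under 3 settings. WT regions outnumber DE regions in the lists as deposited (3456 against 432) and at −log10 q of at least 5 (2692 against 99), and not with lists of equal length (929 against 1087).

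The strongest region called only in WT lay inside Zfp949, a zinc finger gene, at 88553235 to 88553334 of chromosome 9. It ranked in the top 0.0155% and 0.032% of the WT lists. The next was near Zfp119b, another zinc finger gene, at 55932100 to 55932278 of chromosome 17, in the top 0.473% and 4.15%. The others of the 10 strongest were nearest to Cd163l1, Tafa5, Lrrfip1, Rfc3, Vti1b, Ly86 and, for 2 separate regions 12.3 and 17.5 kb from its end, Gas8. The region of Vti1b, a SNARE protein of vesicle fusion, was the only one of the 10 within 1 kb of a gene end. Several of the 10 were narrow with many fragments in WT replicates 1 and 2. The Zfp949 region held 136 and 138 fragments in 100 bp, and the Zfp119b region 89 and 140 in 179 bp. The Rfc3 region held 62 and 108 in 99 bp and the Tafa5 region 59 and 57 in 117 bp, against 19 to 43 at the others. Of the regions called only in DE, the first by rank, inside Wwc1 at 35943888 to 35944291 of chromosome 11, ranked in the top 19.7% and 10.8% of the DE lists. It was followed by regions nearest to Alkbh8, Prkce, Tcf7l1, Kif1b, Frmd6, Frat2, Tnfrsf10b, Gsr and Def8. The Alkbh8 region, 3024412 to 3024534 of chromosome 9, lay 311 kb from that gene. It held 207 and 266 fragments in 123 bp, against 11 to 23 at the other 9. None of the regions named here, called only in WT or only in DE, was checked against repeats or a blacklist.

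The third question was which WT regions were missing from the DE lists. Loss was more frequent in regions weak in WT and in regions away from gene ends. Of 18854 regions called in both WT libraries, 18.3% were called in neither DE library. The share was 0.318% in the strongest of 10 WT rank classes and 55.3% in the weakest. Weak peaks drop out of a shorter list more often, and both DE lists were shorter. The trend with rank therefore does not show that weak regions changed more. Regions within 1 kb of a gene end were lost less often (11.4%) than other regions (27.8%). At equal WT rank, 14.7% of the gene-end regions would have been lost, and the exact stratified test gave p = 6.8e-52 (two-sided). Regions are not independent replicates, so this p describes these 4 lists and not the genotypes.

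**Figure D5:**
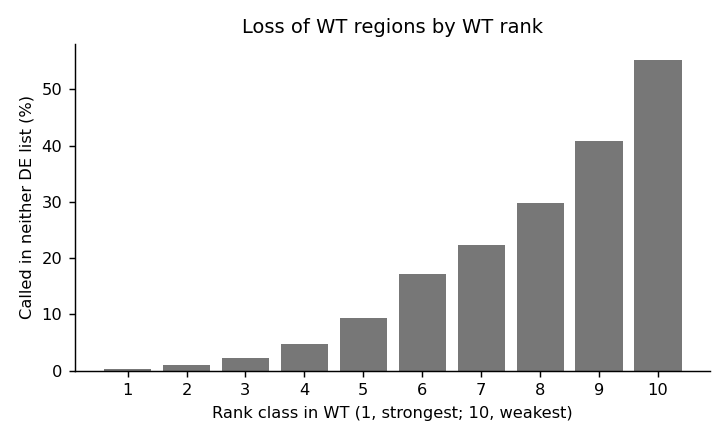
Share of the H3K4me2 regions of both WT libraries that was called in neither DE list (vertical axis, %), by rank class in WT (horizontal axis, class 1 strongest, 1885 or 1886 regions per class). The share is 0.318% in class 1 and 55.3% in class 10; a shorter list alone would lose weak regions first.

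Among 16 gene lists fixed in advance, regions of granulocyte genes were lost less often than others of like rank. All 28 regions, at Mpo (myeloperoxidase), Elane (neutrophil elastase), Prtn3, Ctsg (cathepsin G), Gfi1, Cebpa and Csf3r, were called in at least 1 DE library, where 5.14 losses were expected. The exact stratified test gave p = 0.00185, and 0.0296 after Benjamini-Hochberg adjustment over the lists. The 28 regions lie at 7 genes and are not independent replicates. The call did not hold without strata (adjusted p = 0.0920 by Fisher's exact test) or with presence by 50% cover, where 1 of 12 regions was lost (2.202 expected, adjusted exact p = 0.942). Without the regions of Mpo, Prtn3 or Ctsg the loss was still 0, of 20, 21 and 24 regions, but the expected numbers were 2.76, 4.02 and 4.19 and the adjusted p 0.317, 0.141 and 0.101. With lists of equal length it was 0 of 18 (1.58 expected, adjusted exact p = 1), too few expected for a loss of 0 to pass. The adjusted p was 0.0112 without WT replicate 2 (10 of 42 lost, 18.2 expected), and 0.143, 0.566 and 0.229 without WT replicate 1, DE replicate 1 and DE replicate 2.

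None of the remaining lists passed the adjusted threshold. Stem and progenitor genes lost 5 of 60 regions, at Hlf, Lmo2, Myb and Tal1 (11.1 expected, exact p = 0.0266, adjusted 0.213). Regulators linked to ZEB2 lost 4 of 38, at Zeb1, Batf3 and Cebpb (8.29 expected, adjusted exact p = 0.317). The genes named for the stem and progenitor and the ZEB2-linked lists are those that held the lost regions, not the first in the fixed order. Monocyte and macrophage genes lost 9 of 59 (10.4 expected), dendritic cell genes 3 of 24 (3.69 expected) and E proteins with their ID inhibitors and partners 5 of 40 (6.36 expected). C/EBP and PU.1 core regulators lost 5 of 61 (9.38 expected), antigen presentation genes 1 of 21 (3.36 expected), interferon response genes 2 of 10 (2.27 expected), cell cycle genes 4 of 24 (3.84 expected) and housekeeping genes 5 of 34 (5.47 expected). Lists of other lineages had few regions. T cell genes lost 2 of 5, NK and innate lymphoid genes 3 of 9, erythroid and megakaryocyte genes 3 of 14, and the B cell list and the mast cell, basophil and eosinophil list 0 of 1 each. Single libraries decided some of these outcomes. Without WT replicate 2 the adjusted p from the exact test was 0.00387 for stem and progenitor genes, 0.00125 for C/EBP and PU.1 regulators and 0.0319 for antigen presentation, each with fewer losses than expected. Without DE replicate 1 it was 0.0350 for the regulators linked to ZEB2.

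At the gene ends of the 251 listed genes, 7 were called in both WT and neither DE library. They were Cx3cr1, the fractalkine receptor of monocytes, Batf3, a transcription factor of conventional dendritic cells, Clec10a and Cadm1 of the dendritic cell list, Cd247, a chain of the T cell receptor complex, the interferon-induced Ifit2 and the topoisomerase gene Top2a. In both DE and neither WT library 3 were called, namely S100a8, a calcium-binding protein of neutrophils, Nkg7, a granule protein of cytotoxic cells, and Klf1, a transcription factor of the erythroid lineage. Klf1 had a single region, 84902696 to 84903547 of chromosome 8, which was called in all 4 lists and reached into the 1 kb window in DE alone. When calls within 2 kb were counted, Nkg7 alone had the DE pattern. In all 4 libraries 100 genes were called. With lists of equal length, 0 genes had the WT pattern and 8 the DE pattern. Granulocyte genes with a call numbered 7 and 8 in WT and 9 and 11 in DE, a count that depends on the window. The Csf3r peak counted in DE replicate 2 alone belongs to a region 999 bp from the gene end that was called in all 4 lists, whereas the region at Cxcr2 was called in DE replicate 2 alone. Clec10a, Cadm1, S100a8, Csf3r and Cxcr2 were singled out after their values were seen.

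The last comparison set H3K4me3 against H3K4me2 in WT cMoPs. Of the 6425 H3K4me3 peaks, 90.2% (95% Wilson interval 89.4 to 90.9) overlapped peaks of both WT H3K4me2 libraries and 3.27% overlapped neither. H3K4me3 peaks lay within 1 kb of a gene end in 76.0%, against 45.0% and 50.2% of the peaks of the WT H3K4me2 lists. In the shorter lists of DE replicates 1 and 2 the share was 53.0% and 58.5%. The H3K4me3 list was shorter still, and how far list length gave the gap was not tested. In the other direction, 28.2% of the WT H3K4me2 regions carried an H3K4me3 peak, 38.4% at gene ends and 14.2% elsewhere. Regions with H3K4me3 were lost from the DE lists in 3.98% (3.49 to 4.54), and regions without it in 24.0% (23.3 to 24.7). At equal WT rank and place 384 losses were expected among the regions with H3K4me3 and 212 were observed (exact stratified p = 8.5e-33, over regions). This test was not part of the fixed design and was not run under the alternatives. Its strata leave out the width of the regions. Regions are not independent replicates, so its p describes these lists and not the genotypes. The 2 marks were profiled in different batches, with 1 H3K4me3 library, so mark and batch cannot be told apart.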

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

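Peak summits on unplaced scaffolds and the mitochondrial genome, which no comparison used, numbered 64 and 51 in WT replicates 1 and 2 and 51 and 29 in DE replicates 1 and 2 for H3K4me2. With no control list, each exceeded the limit of 3 that a count of 0 allows; the H3K4me3 list had 2. This limit is not an expected number for lists of this length.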

How the results depend on the processing

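Leaving out the stretch between Gas8 and Rhou, or one granulocyte gene at a time, was chosen after the data were seen. The peak-number difference kept its direction in every alternative run (−0.87 on the log2 scale at −log10 q of at least 5, and −0.82 to −0.46 without each replicate). The overlap difference (0.0448 to 0.0807) and the lower loss at gene ends kept their directions too. The size of the latter varied: −3.22 points in the main setting, −12.4 without WT replicate 2 and −1.85 with lists of equal length. The settings run at the searched Zeb2 windows can only remove peaks, so the 0 lists there are not tested by them. The replicate numbers are shared between genotypes but no label makes them pairs; with the replicate block the difference was −0.64 with exact p = 0.5. The Jaccard index was 0.388 and 0.445 for pairs of equal number and 0.361 and 0.497 for crossed pairs. Lists of equal length gave 929 WT-only and 1087 DE-only regions, 0 gene lists past the threshold and 0 listed genes with WT-only calls; the shorter lists themselves remove weak WT peaks. DE-only regions numbered 99 at −log10 q of at least 5, 1048 with presence by 50% cover and 258 when intervals within 500 bp were merged; the cause was not tested. Without 1 replicate, WT-only regions numbered 4317 (DE replicate 2) to 11846 (WT replicate 2) and DE-only regions 720 (WT replicate 1) to 3379 (DE replicate 2), since fewer lists must share the pattern. The number of gene lists past the threshold was 0 by Fisher's exact test without strata and with 50% cover, and 0 to 4 without 1 replicate. Without WT replicate 2 it took in stem and progenitor genes, C/EBP and PU.1 regulators and antigen presentation, and without DE replicate 1 the ZEB2-linked regulators in place of the granulocyte list. H3K4me3 peaks shared with both WT lists were 83.7% at −log10 q of at least 5 and 85.6% with 50% of the peak covered, and 91.6% to 95.3% overlapped a single WT list. Without the Gas8 to Rhou stretch 3436 WT-only and 432 DE-only regions were left. Of 70 alternative values, 36 stayed within the main result's range or call, 25 moved, 9 lost the call and 0 changed sign, each count taken alone. Counts and shares could not change sign. List length and overlap could not gain or lose a call, since their exact tests cannot pass the threshold. These totals therefore overstate how far stability was tested. The balance of counts turned with lists of equal length, from 3456 against 432 regions to 929 against 1087 and from 7 against 3 listed genes to 0 against 8. At a background of 1 a called summit held at least 6 and 7 fragments in WT and 8 and 9 in DE. The fewest in any called summit were 3 and 5 in WT and 5 and 6 in DE. None of these fragment numbers is scaled to depth.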

Other observations

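Of the tests in this part, those of lower enrichment, of the Gas8 to Rhou stretch against like regions and of granulocyte fragments were set before their results were seen, and the others after. Between Gas8 and Rhou (chromosome 8, 123536657 to 123653929) 96 H3K4me2 regions were called over 117 kb, in WT replicates 1 and 2 in 92 and 63 and in DE replicates 1 and 2 in 42 and 28. Of these 20 were called in both WT and neither DE library and 0 the other way, and 28 were called in all 4. At the 6 regions around Zeb2 called in all 4 lists, the median log2 ratio of depth-scaled fragments, DE to WT, was −0.29, at percentile 85.8 of 10000 random sets of regions of like WT rank (95% of sets between −0.85 and −0.15). Among the 16 fixed lists, over their regions called in all 4 lists, the lowest percentile was that of housekeeping genes (0.55, 23 regions, median log2 ratio −0.84). The two-sided resampling p from its random sets was 0.011, and 0.176 after adjustment, so no list passed. The sets drew regions 1 by 1 with replacement, as if regions were independent.

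The DE lists were shorter than the WT lists. Lower sequencing depth is argued against, since the shallower DE library had 1.15 times the relative depth of the deeper WT library. Joining of neighbouring intervals is argued against too, since the DE lists also called fewer merged regions (0.677 times the WT mean). Weaker enrichment over background in the DE libraries may account for the pattern: at 11886 regions called in all 4 lists the median depth-scaled fragments were 29.4 and 27.9 in WT and 20.02 and 17.0 in DE, a ratio of 0.717 between the higher DE and the lower WT value. Whether this comes from the genotype or from the handling of the libraries was not tested and stays open with 2 libraries per genotype. The inferred fragment length, which also differed between the genotypes, was not taken into account.

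The stretch between Gas8 and Rhou had weaker calls in DE. The median log2 ratio of its 28 shared regions was −1.99. Of 10000 random sets of like WT rank, 95% fell between −0.92 and −0.61 and 0 were as low. However, the stretch was picked after the data were seen and holds regions named above among the strongest called only in WT. Its regions also lie side by side, while the sets drew regions over the genome. The sets therefore cannot show whether lower enrichment over all regions alike could give such a stretch. Its shared regions lay at a median spacing of 1.71 kb, and a repeat whose number of copies differs between the animals may underlie the weaker calls. It cannot be told apart from a change of the mark, because peak lists give no fragments outside peaks. A difference between the enhancer variants also stays open, as untested.

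All 28 granulocyte regions of both WT lists were called in at least 1 DE library, though 1 was not called in DE replicate 1 and 4 not in DE replicate 2, and 5 of 23 regions were called in both DE and neither WT library with lists of equal length (2.28 expected, exact p = 0.0489, adjusted over the lists 0.446). In the lists as deposited it was 1 of 29, with 1.06 expected (exact p = 1). More granulocyte-lineage chromatin in the DE sorts could give this. Depth-scaled fragments were compared only over the list's 23 regions called in all 4 lists, at 7 genes. They stood at percentile 87.0 of random sets (median log2 ratio −0.49), within the range of chance. Regions called in DE alone, such as that at S100a8, were left out. The comparison therefore cannot decide whether granulocyte regions were gained in DE. Several genes of the granulocyte list, such as Mpo and Elane, are also expressed in early myeloid progenitors. A difference in list length cannot be told apart from such a gain either, since the excess with lists of equal length did not pass the adjustment.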
